A study of Mus musculus with 3 samples.

How the data were processed

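Single-cell RNA was measured in 3 libraries of sorted mouse retinal horizontal cells, 1 library each from postnatal day 6 (P6), day 8 (P8) and day 11 (P11). Per the labels' protocols, cells carrying the Cx57icre and Ai14 alleles were released with papain, sorted by fluorescence and captured with the 10x Genomics 3' droplet chemistry, aiming at 10000 cells. In that chemistry each captured transcript receives a unique molecular identifier (UMI), so that a count is a count of molecules near the 3' end and not of PCR copies. The authors deposited raw UMI counts for each gene and barcode, made with Cell Ranger 7.1.0 on the mouse build mm10, per the submitters' processing notes. The annotation release and whether intron reads were counted are not given in the sources used here. The deposited matrices held 32285 features and 9896 (P6), 4635 (P8) and 5517 (P11) barcodes, none with fewer than 500 UMIs. Their totals were 87939202, 65546590 and 105561999 UMIs.

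Gene positions came from the GENCODE vM21 annotation of the same build, in which 32158 of the features had a match by gene ID. The 78 features that shared their symbol with another feature were left out of the named genes and lists, among them Aldoa of the glycolysis list.

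Barcodes with at least 1000 detected genes and at most 10% of UMIs from mitochondrial genes were kept. Barcodes below the gene minimum numbered 1513 at P6, 1034 at P8 and 408 at P11, and a further 811, 319 and 166 exceeded the mitochondrial limit. Scrublet scores were computed with scanpy 1.11.5. The caller's own threshold marked 0%, 0.244% and 0% of cells, which was under the working minimum of 0.5%, so the score reached by the doublet rate usual for the loading (0.8% per 1000 cells, or 6.06%, 2.63% and 3.95%) served as the limit. Cells at or above that score, ties included, were removed, 512 (6.76%) at P6, 165 (5.03%) at P8 and 230 (4.65%) at P11. The kept cells numbered 7060 (71.3% of barcodes), 3117 (67.2%) and 4713 (85.4%). Their median UMIs were 11460, 20422 and 21760.

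Each library was clustered separately with the Leiden method at resolution 1, using 2000 variable genes, 30 principal components and 15 neighbours. Genes of the study-question lists were kept out of the variable genes. A cluster received a name ending in "-like" when at least 3 markers of a class were detected in it and its leading genes did not go against the name. A marker counted as detected in a cluster when at least 20% of its cells held a UMI and its level was at least 50% of that in the highest cluster. Classes other than horizontal cells also needed at least 2 of their own markers among the top 10 genes by fold. Clusters with a median UMI count far below that of their library and no marker of their class among their top 10 genes by fold stayed unnamed. Marker lists covered 14 classes, namely horizontal cells, rods, cones, bipolar cells, amacrine cells, ganglion cells, Müller glia, cycling progenitors, microglia, endothelial cells, pericytes, astrocytes, pigment epithelium and erythroid cells.

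Raw counts of the horizontal-like cells were summed per library and divided by the summed UMIs to give counts per 1000000 UMIs (CPM). With 1 library per age no test between ages was possible. Sums carry exact Poisson 95% intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all of which cover counting error only. A gene entered a comparison when its higher age had at least 20 CPM, and was counted when its ages lay at least 2-fold apart. A count of 0 entered a ratio with a floor of 3 counts. The ribosome list was taken by the start of the gene symbol and so also holds a few kinase genes such as Rps6ka3. The oxidative phosphorylation list was taken in the same way, and its symbol starts also match assembly factor genes (symbols starting with Ndufaf).

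The 17 gene lists are described by the number of measured members at least 1.5-fold higher, at least 1.5-fold lower and between, by the median log2 ratio, and by the percentile of that median among 10000 random lists of equal size matched on mean expression. Genes were named by fixed rules. The 12 highest and 12 lowest P11 to P6 ratios were taken among genes with at least 50 CPM at the higher age whose P8 value lay between the other ages and whose level was at least 25% of that in every other named class of its library with at least 50 cells. Mitochondrial, ribosomal, hemoglobin, Xist, Tsix and Y-linked genes and provisional symbols were left out there. From each list the members farthest above and below 1.5-fold, at most 2 each way, were added, together with Ank1, Ank2 and Ank3. Some genes that these rules name are not reported here. To compare shares of cells with an ankyrin UMI, every cell was thinned to 3000 UMIs and shallower cells were left out.

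A planned edgeR comparison of horizontal-like cells with other cell classes was not run, since no other named class reached 50 cells in every library. An edgeR 4.0.16 quasi-likelihood test, with TMM scaling, filterByExpr, the library as a block and Benjamini-Hochberg adjustment at 0.05, was used once, between sets of horizontal-like clusters within the libraries. DESeq2 1.42.0 was its alternative. The calculation of the age ratios was checked on Poisson counts simulated for 6654 genes of P11 over P6, with no variation between libraries. All 100 genes made 3-fold different were counted, and 0 of 100 made 1.5-fold different and 0 unchanged genes. The ratio intervals covered the true value for 95.3% of genes. At this depth these outcomes were close to fixed in advance, so they check the calculation and not false calls between single libraries. Of 200 unshifted random lists 7 fell outside the central 95%, and 20 of 20 lists shifted by -0.5 log2 fell below it. The unshifted lists were drawn at random with genes varying independently, so their outcome was also close to fixed in advance. They do not test lists whose genes move together between libraries. The edgeR step was tested on simulated counts of 14615 genes for the set comparison. It recovered 98 of 100 genes changed 1.5-fold and 100 of 100 changed 2-fold, with 6 unchanged genes called.

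The groups, the filters, the clustering settings, the markers, the gene lists, the naming rules and the alternatives were chosen before the data were examined, except where the closing section says otherwise. The fallback for doublets and the rule on leading genes of clusters were settled afterwards. Alternatives covered at least 2000 genes per cell, at most 5% mitochondrial counts, doublets kept, joint clustering, a marker gate on at least 2 of Lhx1, Onecut1 and Onecut2, TMM factors, median-of-ratios size factors, CPM without mitochondrial and ribosomal genes, means over cells, thinning, subtraction of the profile of other cells, and CPM minimums of 5 and 100. Analyses ran in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, igraph 0.11.9 and scikit-learn 1.9.0, and in R 4.3.3. Figures were drawn with matplotlib 3.10.9.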

Results

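Horizontal cells are inhibitory interneurons of the outer retina whose processes meet the terminals of rods and cones in the outer plexiform layer. The mice carried Cx57icre, a Cre driver made from the connexin 57 gene that is active in horizontal cells, together with Ai14, a reporter that makes a red fluorescent protein after Cre has acted. Red cells were sorted at P6, P8 and P11, days on which horizontal cells contact photoreceptor terminals, and each sort gave 1 droplet library. Ankyrins are adaptor proteins that tie membrane proteins to the spectrin skeleton, and the series title names them in synapse development. The comparison asked by this design is therefore which genes, ankyrins first, differed between the ages in horizontal cells. There were no replicates, so age and library cannot be told apart, and intervals cover counting error only.

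The deposited counts came to 87939202 UMIs over 9896 barcodes at P6, 65546590 over 4635 at P8 and 105561999 over 5517 at P11. After filtering, 7060, 3117 and 4713 cells remained. Horizontal-like cells were 6087 of these at P6 (86.2%, exact binomial 95% interval 85.4 to 87.0%), 2766 at P8 (88.7%, 87.6 to 89.8%) and 4343 at P11 (92.1%, 91.3 to 92.9%), in suspensions that had been sorted for them. Their median depth was 12324, 21021.5 and 22177 UMIs per cell, and their summed counts were 72271671, 57242242 and 95847082 UMIs.

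The horizontal-like cells carried the transcription factor genes of this lineage at each age. Lhx1 stood at 709.6 counts per 1000000 UMIs (CPM) at P6, 830.8 at P8 and 794.6 at P11, and Onecut1 at 767, 692 and 686 CPM. Calb1, which encodes the calcium buffer calbindin, was higher at each later age, with 715, 1723 and 2970 CPM. The anion exchanger gene Slc4a3 stood at 497.5, 829 and 2150 CPM. Gja10, the gene of connexin 57 itself, was low throughout, at 9.88, 25.98 and 25.6 CPM.

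Few other cells were named. Müller-like glia made up 60 cells at P6 (0.850%) and 13 at P11 (0.276%), rod-like cells 45 at P8 (1.44%) and 42 at P11 (0.891%), and bipolar-like cells 93 at P11 (1.97%). Unnamed clusters held 913 cells at P6 (12.9%), 306 at P8 (9.82%) and 222 at P11 (4.71%). Of these, 615 cells (8.71%), 244 (7.83%) and 204 (4.33%) sat in clusters of low UMI count that carried horizontal cell markers. Among the top 10 genes by fold of the P6 cluster, 0 were horizontal cell markers and 1, Lrtm1, was a bipolar marker. With those clusters included, an alternative chosen after seeing the data, the horizontal-like share came to 94.93% at P6, 96.57% at P8 and 96.48% at P11, so the order of the shares depends on them.

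Within the horizontal-like cells, the summed markers of photoreceptors were low at every age. Rod markers came to 5.67, 4.98 and 5.38 CPM and cone markers to 1.18, 0.978 and 1.43 CPM at P6, P8 and P11. Microglial markers stood at 9.91, 4.87 and 4.33 CPM, endothelial markers at 10.4, 10.9 and 9.84, pericyte markers at 4.57, 3.95 and 3.84, and markers of cycling progenitors at 3.61, 3.16 and 3.18. Astrocyte markers reached 2.05, 0.664 and 0.918 CPM, pigment epithelium markers 0.609, 0.332 and 0.365, and erythroid markers 2.06, 0.280 and 0.605. Müller glia markers stood at 211, 204 and 299 CPM and bipolar markers at 115, 48.6 and 52.1. Most of the bipolar sum was Prkca, at 101.8, 44.25 and 47.84 CPM. Most of the Müller sum was Glul, at 123, 138 and 196 CPM, followed by Clu and Dkk3, while Rlbp1 and Slc1a3 were under 1 CPM. The sums of amacrine markers (6864, 9275 and 4484 CPM) and ganglion cell markers (795, 936 and 559 CPM) rested almost wholly on Npy, a neuropeptide gene, and on Sncg, the gene of gamma-synuclein. Markers fixed for horizontal cells summed to 9763, 14050 and 20040 CPM.

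The 3 ankyrin genes stood at very different levels in horizontal-like cells, and the 2 abundant ones differed from each other in how they compared across age. Ank2, which encodes ankyrin-B, was the most abundant, with 1931 CPM at P6 (1921 to 1942), 1419 at P8 (1409 to 1428) and 2122 at P11 (2113 to 2131). Ank3, which encodes ankyrin-G, the organiser of axon initial segments, stood at 530.5 CPM at P6 (525.2 to 535.8), 193.8 at P8 (190.2 to 197.4) and 276.2 at P11 (272.9 to 279.5). P11 thus had 1.10 times the Ank2 level of P6 (log2 ratio 0.14) but 0.521 times the Ank3 level (log2 ratio -0.94). Ank1, the ankyrin of red blood cells that some neurons also make, was near 3 CPM or less, with 3.10 CPM at P6 (2.71 to 3.53), 1.21 at P8 (0.938 to 1.53) and 1.27 at P11 (1.06 to 1.52).

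**Figure D1:**
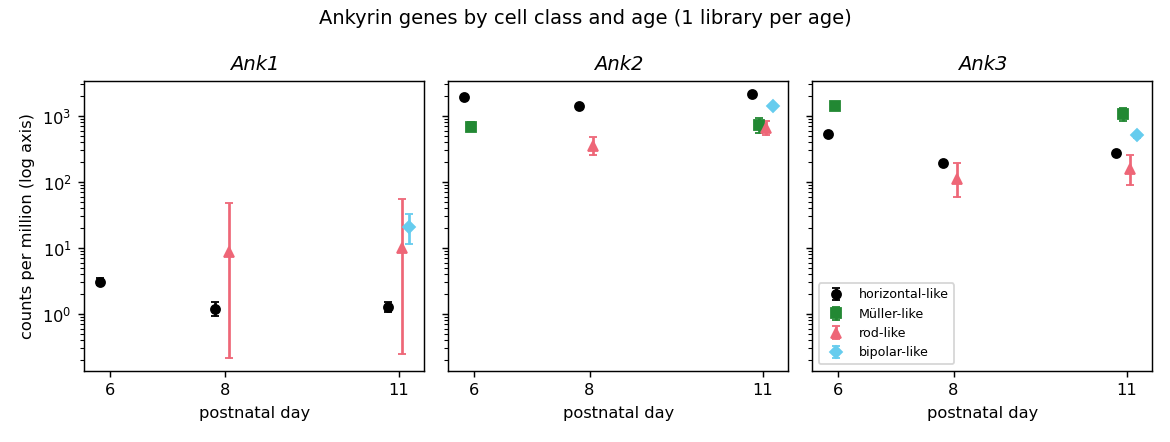
CPM of Ank1, Ank2 and Ank3 at P6, P8 and P11 in horizontal-like, Müller-like, rod-like and bipolar-like cells, where a UMI was counted. Bars are exact Poisson 95% intervals that cover counting error only. In horizontal-like cells Ank2 and Ank3 are both lowest at P8, at 1419 and 193.8 CPM. At P11 Ank2 is above its P6 level there while Ank3 is below it.

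Both genes were lowest at P8. The log2 ratio of P8 over P6 was -0.45 for Ank2 and -1.45 for Ank3, and that of P11 over P8 was 0.58 and 0.51. These ratios moved with gene length in the P8 library: Ank2 and Ank3 span 578 and 629 kb, and among genes in the longest of 5 span groups (median 162 kb) the median log2 ratio of P8 over P6 was -0.73, against 0.27 in the shortest group (4.80 kb). The nuclear RNA Malat1 was also lowest at P8, at 19580, 14050 and 20970 CPM for P6, P8 and P11. For P11 over P6 the corresponding medians were -0.28 and 0.00.

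**Figure D2:**
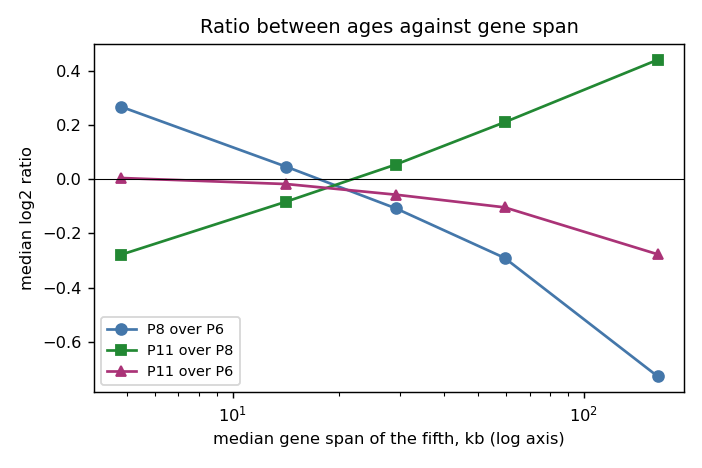
Median log2 ratio between ages in horizontal-like cells for genes in 5 groups of increasing gene span, from a median of 4.80 kb to 162 kb. P8 over P6 runs from 0.27 in the shortest group to -0.73 in the longest, and P11 over P8 runs the other way.

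At the level of single cells thinned to 3000 UMIs, an Ank2 UMI was found in 98.7% of horizontal-like cells at P6, 96.4% at P8 and 99.1% at P11, and an Ank3 UMI in 75.4%, 42.9% and 52.3%. Ank1 was seen in 0.971%, 0.443% and 0.394%. Without thinning the shares were 99.9% at all ages for Ank2, 95.6%, 92.9% and 97.0% for Ank3, and 3.45%, 2.28% and 2.63% for Ank1. The thinning left out 116, 55 and 30 shallower cells. Ank3 was higher in Müller-like cells, at 1433 CPM at P6 (1284 to 1595) and 1057 at P11 (844.5 to 1307), than in horizontal-like cells of the same libraries, whereas Ank2 was lower there, at 690.9 and 721.5 CPM. In rod-like cells, 41 Ank2 UMIs and 13 Ank3 UMIs were counted at P8 (353 and 112 CPM) and 66 and 16 at P11 (653 and 158 CPM), which are too few to tell expression from free RNA of the horizontal cells around them. The droplets of 93 bipolar-like cells at P11 (median 5034 UMIs) held 1414 CPM of Ank2, 508 of Ank3 and 20.4 of Ank1, the last from 16 UMIs. Free horizontal cell RNA was not subtracted from any of these classes, so Ank2, which was below the horizontal-like level in each of them, cannot be told from such RNA there. After thinning, Ank3 was seen in 87.0% of 23 Müller-like cells at P6 (66.4 to 97.2%) and 41.7% of 12 rod-like cells at P8 (15.2 to 72.3%), an interval too wide to set against the horizontal-like share. With cells thinned to 1500 UMIs, Ank3 was seen in 15.9% of 44 rod-like cells at P8 (6.64 to 30.1%) and in 25.1% of horizontal-like cells (23.4 to 26.7%). Median depth was 2479 UMIs in the Müller-like cells and 2371 in the rod-like cells of these libraries.

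In the mm10 build, Ank1 (ENSMUSG00000031543) lies on chromosome 8 from 22974844 to 23150497, Ank2 (ENSMUSG00000032826) on the minus strand of chromosome 3 from 126921612 to 127499350, and Ank3 (ENSMUSG00000069601) on chromosome 10 from 69398773 to 70027438. The counts are per gene and do not tell apart the isoforms of Ank2 and Ank3, some of which carry a giant exon used in axons.

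The genes of the ankyrin and spectrin skeleton, Ank2 and Ank3 among them, showed no common direction between P6 and P11. Of 11 measured members of this list 2 were at least 1.5-fold higher at P11, 3 were lower, Ank3 included, and 6 lay between. Their median log2 ratio of -0.03 (57.2nd percentile of matched random lists) turned positive under TMM and median-of-ratios scaling, with at most 5% mitochondrial counts, as a mean over cells, after thinning and at a minimum of 100 CPM. The adducin genes Add3 and Add1, whose proteins cap actin filaments at spectrin junctions, were 1.91 and 1.55 times as high at P11. Membrane proteins that bind ankyrins were lower at P11 as a group: 0 of 12 were at least 1.5-fold higher and 7 were lower (median log2 ratio -0.63, 0.01st percentile). At a minimum of 100 CPM only 3 of these genes were left, and their median of -0.22 was at the 38.2nd percentile. The group result is thus not shown for the more abundant genes alone, where 3 genes are too few to judge it. The potassium channel gene Kcnq3, 1 of these 3, stood at 148 CPM at P6, 19.0 at P8 and 7.22 at P11. The less abundant sodium-calcium exchanger gene Slc8a1 was 7.001-fold lower at P11 than at P6.

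Over all genes, the horizontal-like cells at P11 had more RNA for Mgarp, Tkt, Vim and most glycolysis genes than those at P6, and much less for Pyy, Marcksl1 and most neurite growth genes. Of 7137 genes with at least 20 CPM at the higher of these ages, 169 were at least 2-fold higher and 322 at least 2-fold lower at P11, and P8 lay between for 137 and 236 of them. TMM scaling moved the median of all genes by 0.18 log2 and gave 261 higher and 225 lower, and median-of-ratios scaling 261 and 220, so the balance of higher and lower genes rests on the scaling. The share of higher genes went from 34.4% to 53.7% and 54.3%.

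Ratios of single genes were ranked among genes with at least 50 CPM at the higher age, with P8 between the other ages and within the other limits of the naming rule. The gene with the highest ratio there was Rskr, a ribosomal S6 kinase related gene, at 0.761 CPM at P6, 6.06 at P8 and 62.9 at P11, an 82.6-fold ratio (63.4 to 110). Mgarp, whose product is a mitochondrial protein and which was among the horizontal cell markers, stood at 163.5, 2642 and 5465 CPM, a 33.4-fold ratio (32.8 to 34.0). Lynx1, a brake on nicotinic acetylcholine receptors, was 11.5-fold higher at P11, and Ly6e of the same protein family 4.52-fold. Thrsp, a regulator of lipid synthesis, was 8.38-fold higher, and Tkt, the transketolase of the pentose phosphate pathway, went from 191 CPM at P6 to 437 and 1341. The metal-binding protein gene Mt1 was 8.17-fold higher, and Rgs9bp, which anchors a regulator of G protein signalling, 7.25-fold. Vim, an intermediate filament gene that glia also express, stood at 798, 2577 and 3662 CPM. The remaining genes among the highest 12 were Vstm2a (4.998-fold), the phosphatase gene Dusp10 (4.99-fold) and the transcription factor gene Bhlhe40 (4.78-fold).

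The gene with the lowest ratio under the same limits was Pyy, which encodes peptide YY, at 225 CPM at P6, 16.6 at P8 and 0.209 at P11, where 20 UMIs were counted. It was 1078-fold lower at P11 (698 to 1765). Marcksl1, an actin-regulating gene of growing neurites, was 147.8-fold lower at P11, with 168, 25.8 and 1.14 CPM. The microRNA host transcript Mir670hg was 34.6-fold lower, Filip1l 25.3-fold, Ly6h 23.1-fold and Nt5dc2 22.7-fold. Nnat, an imprinted gene of developing brain, stood at 844, 320 and 42.4 CPM. The receptor tyrosine kinase gene Alk stood at 246, 36.0 and 12.9 CPM, and Rgs4, a brake on G protein signalling, was 18.1-fold lower at P11. The channel-associated gene Dpp10 was 20.6-fold lower at P11 and the AMPA receptor subunit gene Gria1 17.0-fold. Kcnq3, described with the ankyrin-bound proteins, was also among the lowest 12 under these limits. Gad1, with 39.3 CPM at P6, was under the 50 CPM minimum and was 63.9-fold lower at P11.

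**Figure D3:**
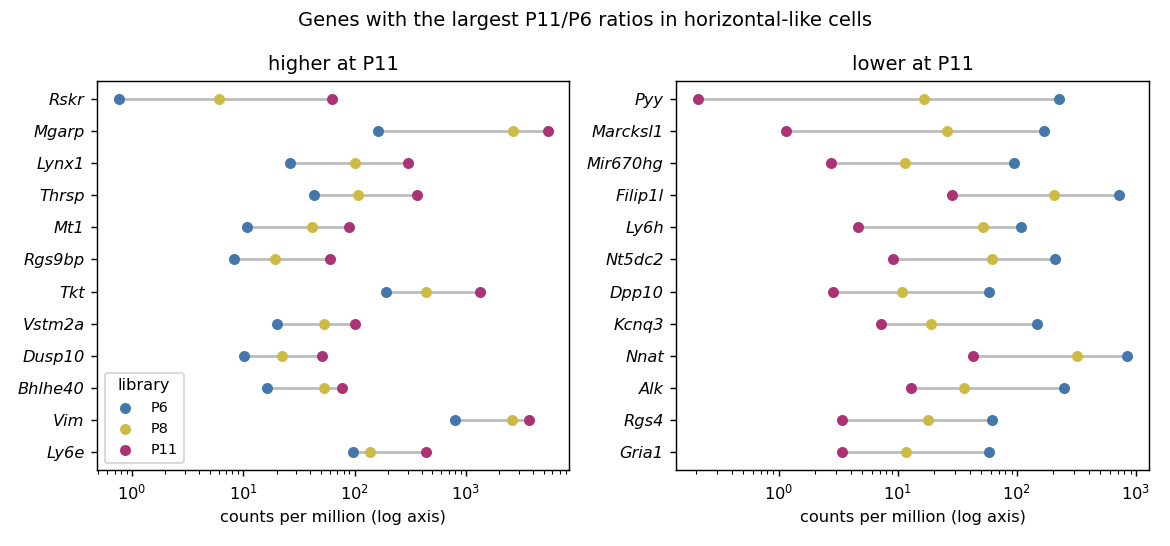
CPM at P6, P8 and P11 of the 12 genes with the highest and the 12 with the lowest P11 to P6 ratio in horizontal-like cells, on a log axis, among genes with at least 50 CPM at the higher age and P8 between the other ages. They run from Pyy at 225 CPM at P6 and 0.209 at P11 to Rskr at 0.761 and 62.9.

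Genes of immature neurons and growing neurites were the most clearly lower group at P11. Of 21 measured, 15 were at least 1.5-fold lower and 1, the tubulin gene Tubb2a (1.59-fold), was higher, with a median log2 ratio of -1.22 that lay below all 10000 matched random lists. The mature cytoskeleton list was split, with 3 of 12 higher and 5 lower (median -0.48, 0.37th percentile). Tuba4a was 4.41-fold and Tubb4b 1.73-fold higher, while Nefm, a neurofilament subunit gene, stood at 1247, 740 and 402 CPM and the microtubule-associated protein gene Map1b was 2.86-fold lower.

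Adhesion and guidance genes were mostly lower at P11 than at P6. Among synaptic adhesion genes 17 of 27 were at least 1.5-fold lower and 1 was higher (median log2 ratio -0.79, below all random lists). The higher one was Lrrc4, a netrin-G ligand gene, at 2.10-fold, while its relative Lrrc4b was 3.65-fold lower and the teneurin gene Tenm2 4.50-fold lower. Among genes of mosaic spacing and axon guidance 11 of 19 were lower and 1 was higher (median -0.90, below all random lists). The ephrin receptor gene Epha7 was 1.80-fold higher, and the ephrin gene Efna5 and the receptor gene Ephb2 were 3.51-fold and 3.49-fold lower. Cadherins were more mixed, with 3 of 10 lower and 1 higher (median -0.35, 3.86th percentile). Pcdh17 was 1.68-fold higher, Pcdh15 9.04-fold lower and Cdh10 2.56-fold lower. Adhesion, guidance and cadherin genes are long, with median spans of 170, 277 and 318 kb. Against random lists matched on gene span as well, the medians of the adhesion and guidance lists were still below all 10000, and that of the cadherins was at the 37.0th percentile. At a minimum of 100 CPM the guidance list stayed below the central 95% of random lists, while the adhesion list, with 16 genes and a median of -0.32, was at the 2.63rd percentile.

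Receptors and channels were lower at P11 as groups, while the vesicle release machinery was not. Of 23 glutamate receptor and postsynaptic genes 11 were at least 1.5-fold lower and 0 higher (median -0.49, below all random lists), among them Gria1 and the kainate receptor accessory gene Neto1, which was 8.23-fold lower. Of 9 GABA genes 5 were lower and 0 higher (median -0.63, 0.34th percentile). Gad1, which encodes a GABA-synthesising enzyme, stood at 39.3 CPM at P6, 7.74 at P8 and 0.616 at P11, and the receptor subunit gene Gabrb2 was 6.19-fold lower. At a minimum of 100 CPM neither list was below the central 95% of random lists. There 12 glutamate genes had a median of -0.30, at the 9.235th percentile, and 4 GABA genes a median of -0.48, at the 3.01st. Of 14 ion channel and gap junction genes 6 were lower and 0 higher (median -0.51, 0.19th percentile, or the 5.80th with gene span matched). The potassium channel gene Kcnd3 was 5.41-fold lower and its partner Kcnip4 2.63-fold lower. Of 27 vesicle release genes 25 lay within 1.5-fold (median -0.08, 38.4th percentile), with a sign that turned under both other scalings. The exceptions were Cplx1, a complexin gene, 5.79-fold lower, and Rph3a, 1.53-fold lower.

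Genes of energy metabolism were the groups that were higher at P11. Of 15 glycolysis genes 8 were at least 1.5-fold higher and 1 was lower (median log2 ratio 0.64, above all 10000 random lists). The aldolase gene Aldoc was 3.21-fold and the phosphofructokinase gene Pfkl 2.24-fold higher, while the isozyme gene Pfkp was 2.52-fold lower. Of 85 oxidative phosphorylation genes 76 lay within 1.5-fold, 8 were higher and 1 was lower, yet the median of 0.19 was at the 99.98th percentile. Ndufa1 and Ndufa10 were 1.93-fold and 1.57-fold higher and Cox6a1 was 1.68-fold lower. Cytosolic ribosomal protein genes were slightly lower at P11, with 14 of 87 at least 1.5-fold lower and 0 higher (median -0.33, below all random lists), led by Rps26 (2.33-fold lower) and Rpl23a (2.27-fold lower).

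The remaining lists differed little between P6 and P11. The transcription factors of horizontal cells lay within 1.5-fold for 10 of 12 genes (median -0.07, 34.3rd percentile), with a sign that turned under both other scalings and at minimums of 5 and 100 CPM, and Sall3 and Nfia were 1.64-fold and 1.61-fold lower. Cholesterol synthesis genes had a median of 0.13 (94.7th percentile), with Idi1 1.61-fold higher and Cyp51 1.67-fold lower. All 5 measured immediate early and stress genes lay within 1.5-fold (median 0.20, 85.2nd percentile).

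**Figure D4:**
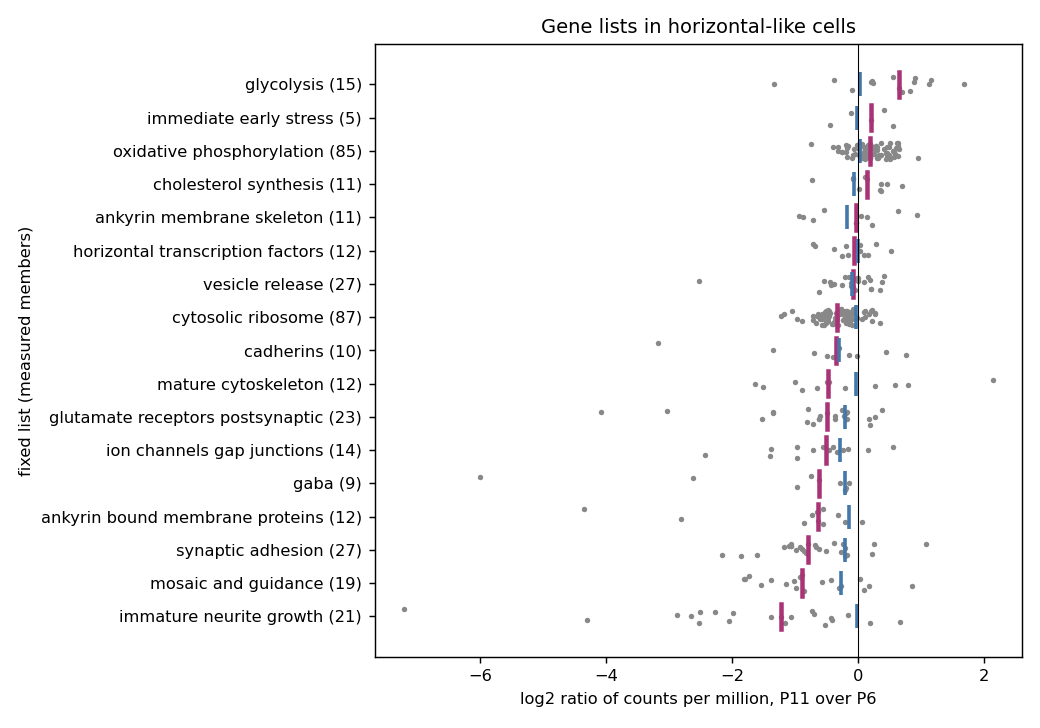
Median log2 ratio of P11 over P6 for the 17 gene lists in horizontal-like cells (bars), with the measured member genes as dots. The tick in each row is the median of random lists matched on gene span and mean expression. Immature neurite growth genes lie lowest at -1.22 and glycolysis genes highest at 0.64; the medians of the ankyrin skeleton, vesicle release and transcription factor lists change sign under TMM and median-of-ratios scaling.

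Taken in steps, more genes lay at least 2-fold apart between P6 and P8 than between P8 and P11. From P6 to P8, 120 of 7045 genes were at least 2-fold higher and 601 lower at P8, but TMM scaling moved the median by 0.26 log2 and gave 309 and 300, and median-of-ratios scaling gave 372 and 268. The share of higher genes was 16.6%, 50.7% and 58.1% under the 3 scalings. From P8 to P11, 149 of 6763 genes were at least 2-fold higher and 70 lower at P11, with 112 and 93 under TMM scaling and 95 and 97 under median-of-ratios scaling (68.0%, 54.6% and 49.5% higher). More genes were also 2-fold apart for P8 over P6 than for P11 over P6 (169 and 322 of 7137). The standard deviations of the log2 ratios were 0.619 for P8 over P6, 0.481 for P11 over P8 and 0.641 for P11 over P6. Ratios with P8 moved with gene span, as given above, so the steps cannot be read as amounts of change with age.

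Immature neurite genes were lower in both steps, with 11 of 21 at least 1.5-fold lower in each and median log2 ratios of -0.67 and -0.73. Glycolysis genes had medians of 0.54 and 0.31, with 6 of 15 at least 1.5-fold higher and 1 lower for P8 over P6, and 0 higher, 1 lower and 14 between for P11 over P8. Oxidative phosphorylation genes had a median of 0.60 for P8 over P6, with 47 of 86 at least 1.5-fold higher and 0 lower, and of -0.41 for P11 over P8, with 0 higher, 14 lower and 72 between. Glutamate receptor, adhesion, guidance and ion channel genes had medians of -0.92, -0.95, -1.19 and -1.05 for P8 over P6 and of 0.46, 0.33, 0.46 and 0.55 for P11 over P8. Those 4 groups are long genes, and both steps moved with gene span and with Malat1 as given above for the ankyrins. With gene span matched, their percentiles for P11 over P8 were 82.4, 28.0, 49.4 and 39.6. For P8 over P6 they were 1.20, 0.515, 0.580 and 9.10.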

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

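The comparison of barcodes with fewer than 1000 genes was chosen after these barcodes had been left out, and no other test was run on it.

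Barcodes below the gene minimum, which enter no comparison of the report, carried transcripts of photoreceptors and red blood cells above the level that a count of 0 allows. They numbered 1513 at P6, 1034 at P8 and 408 at P11, with a median of 819, 717 and 885 UMIs. Sag, the rod arrestin gene, stood at 329.6 CPM in these barcodes at P6, at 378.6 at P8 and at 2678 at P11, against floors of 2.15, 3.54 and 7.72 CPM. In horizontal-like cells of the same libraries it stood at 2.15, 1.12 and 1.51 CPM. The hemoglobin gene Hbb-bs stood at 535.3 CPM there at P6 and at 5137 at P11, while at P8 it had 2 counts, under the floor. In horizontal-like cells Hbb-bs was at 0.125, 0.0699 and 0.136 CPM.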

How the results depend on the processing

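The alternatives that included low-UMI clusters or matched random lists on gene span, and all alternatives of the comparison of Vax2-low clusters, were chosen after seeing the data. The planned comparison of horizontal-like cells with other classes and its alternatives were not run, since no other named class had 50 cells in every library. No paired analysis was possible between ages because each age had 1 library and no test. Of the alternative values of the main results, 196 stayed within their counting interval or within 1.5 times the count and 84 moved. Of the other results 986 stayed and 484 moved. There were 0 sign changes in 766 values of single named genes for P11 over P6. Apart from the ankyrins these genes were picked for ratios of at least 1.5-fold, so a sign change was unlikely from the start. List medians had 19 sign changes in 710 values. At 100 CPM 3 of these medians rested on under 3 genes, and 1 of the 19 was among them, the cholesterol list for P11 over P6, with 1 gene. Counting intervals are narrow at this depth, so small shifts count as moved. Some ratios of single genes shifted more. Across the settings the log2 ratio of P11 over P6 ran from -7.65 to -6.47 for Marcksl1 and from -6.62 to -5.39 for Gad1. For Rgs4 it ran from -4.93 to -3.83, and for Tenm2 from -2.72 to -1.70. Keeping the doublets moved none of the age ratios, gene counts and shares below. Neither did subtracting the profile of other cells, unnamed cells included (0.778%, 0.236% and 0.342% of UMIs at P6, P8 and P11). Neither setting was tried for the comparison of Vax2-low clusters. Where no cause is named the cause was not tested. Depth limited Ank1, with 69 UMIs at P8.

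The log2 ratio of Ank2 for P11 over P6 (0.14) was 0.17 with at most 5% mitochondrial counts, 0.17 with joint clustering, 0.11 with the marker gate, 0.11 with low-UMI clusters included, 0.32 with TMM factors, 0.32 with median-of-ratios factors, 0.17 as a mean over cells and 0.16 after thinning. For Ank3 (-0.94) it was -0.92 with the mitochondrial limit, -0.89 with joint clustering, -0.98 with the gate, -0.99 with low-UMI clusters, -0.76 with TMM factors, -0.76 with median-of-ratios factors and -0.91 after thinning. For P11 over P8, Ank2 (0.58) gave 0.54 with at least 2000 genes, 0.61 with the mitochondrial limit, 0.56 with joint clustering, 0.56 with the gate, 0.56 with low-UMI clusters, 0.50 with TMM, 0.47 with median-of-ratios factors and 0.59 after thinning, and Ank3 (0.51) gave 0.46 with at least 2000 genes, 0.47 with joint clustering, 0.48 with the gate, 0.47 with low-UMI clusters, 0.43 with TMM and 0.40 with median-of-ratios factors. For P8 over P6, Ank2 (-0.45) gave -0.41 with at least 2000 genes, -0.39 with joint clustering, -0.18 with TMM, -0.14 with median-of-ratios factors, -0.43 without mitochondrial and ribosomal genes, -0.41 as a mean over cells and -0.43 after thinning, and Ank3 (-1.45) gave -1.40, -1.36, -1.19 and -1.15 under the same first 4 settings and -1.40 after thinning. Neither gene changed direction in these settings.

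For P11 over P6 the genes at least 2-fold higher (169) came to 261 with TMM, 261 with median-of-ratios factors, 302 at 5 CPM and 65 at 100 CPM, and those lower (322) to 713 at 5 CPM and 108 at 100 CPM. For P11 over P8 the higher genes (149) came to 95 with median-of-ratios factors, 262 at 5 CPM and 64 at 100 CPM, and the lower (70) to 144 and 35 at these minimums. For P8 over P6 the higher genes (120) came to 309 with TMM, 372 with median-of-ratios factors and 61 at 100 CPM, and the lower (601) to 300, 268, 1098 at 5 CPM and 217 at 100 CPM. A higher minimum tests fewer genes. Lists with a median below the central 95% of random lists for P11 over P6 numbered 5 in place of 9 at 100 CPM, where the ankyrin-bound, adhesion, glutamate receptor and GABA lists were lost. Lists above it for P11 over P8 numbered 3 in place of 9 with random lists matched on gene span, where the ankyrin skeleton, adhesion, guidance, cadherin, glutamate receptor and ion channel lists were lost.

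The horizontal-like shares at P6, P8 and P11 (86.2%, 88.7% and 92.1%) were 89.4%, 93.5% and 97.7% with at least 2000 genes, 82.1%, 92.3% and 90.1% with the mitochondrial limit, 83.0%, 96.2% and 96.4% with joint clustering, 94.0%, 95.9% and 96.0% with the marker gate, and 94.9%, 96.6% and 96.5% with low-UMI clusters. P6 had the lowest share in each of these settings, while the order of P8 and P11 turned with the mitochondrial limit and with low-UMI clusters.

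In the comparison of Vax2-low clusters, 28 genes higher and 4 lower became 17 and 1 with DESeq2, and 0 and 0 in edgeR with no replicate block (0 and 0 also at an unadjusted p under 0.05), where the differences between libraries enter the spread. Without a filter 9 were lower, with sets taken by Rassf8 0 were lower, and leaving out 1 library gave 12 to 26 higher and 0 to 6 lower. The count was 12 and 0 without P6.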

Other observations

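The comparison of horizontal-like clusters with low Vax2 was designed after the clusters had been seen, and the splits of its sums and the matching of Ank2 and Ank3 on Malat1 were tests chosen after the result was seen, as were the comparison of Ank2 and Ank3 with genes nearest in span alone and the bounds on ratios from shares of cells, from Malat1 and from markers of other classes.

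Within each library, some horizontal-like clusters had little Vax2, a transcription factor gene of the ventral retina. Clusters with Vax2 under 0.5 of the library's level held 1306 of the horizontal-like cells at P6 (21.5%, 20.4 to 22.5%), 633 at P8 (22.9%, 21.3 to 24.5%) and 1163 at P11 (26.8%, 25.5 to 28.1%). Vax2, which defines the set, stood at 6.03 CPM in it and 52.2 in the remaining horizontal-like cells at P6, 10.0 and 30.9 at P8, and 5.17 and 28.7 at P11. Rassf8 was higher in the set in every library, at 84.6 and 19.9 CPM at P6. The sets were compared by edgeR's quasi-likelihood test on sums, with 3 libraries and the library as a block. Of 494 genes of the fixed lists among 14517 tested, 28 were higher and 4 lower in the Vax2-low set (37 and 7 adjusted over the list alone). Without P6 the list counts were 12 and 0. Over all 14517 genes, which include those used for the clustering, 200 were higher and 63 lower. The clusters were found in the same cells, though without the list genes, so the p-values are only a guide.

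In the Vax2-low set 4 of 17 GABA genes, 4 of 42 synaptic adhesion genes, 4 of 24 guidance genes and 3 of 12 mature cytoskeleton genes were higher under edgeR and 0 of each were lower. Of 29 glutamate receptor and postsynaptic genes 3 were higher and 1 lower, and of 20 cadherins 2 were higher and 2 lower. Immature neurite growth genes had 1 of 22 higher and 0 lower (median log2 ratio 0.03). These counts depend on the libraries and the tool. Without P6 the GABA, adhesion, guidance and mature cytoskeleton lists had 1, 2, 0 and 0 higher, without P8 they had 4, 7, 3 and 0, without P11 4, 1, 4 and 4, and with DESeq2 1, 2, 2 and 3. The genes named here were chosen after their values were seen. Gria1 had a log2 ratio of 0.98 (SE 0.085, adjusted p = 9.4812e-08) and was higher in 3 of 3 libraries, as were the other genes named here as higher. Gap43, a growth cone protein gene, had a ratio of 0.73 (SE 0.074, adjusted p = 1.0592e-06), with 356 and 230 CPM at P6, 251 and 130 at P8, and 60.5 and 38.7 at P11. Neto1 (0.66, adjusted p = 7.3431e-06), Gad1 (0.80, adjusted p = 2.3291e-05) and the neurofilament gene Nefm (0.49, adjusted p = 0.00057246) were higher as well. The NMDA receptor subunit gene Grin2a was lower in the set, with a log2 ratio of -1.17 (SE 0.187, adjusted p = 0.00052267) and in 3 of 3 libraries, but it was not called without P6 (-0.67, adjusted p = 0.4715) or with sets taken by Rassf8 (-0.84, adjusted p = 0.1526). Nefm was not called without P6 or without P8 (adjusted p = 0.05643 and 0.05479), while Gria1, Gap43, Neto1 and Gad1 were called in 7 of 8 alternatives, all but the model without the library. Of the 15 ankyrin and spectrin skeleton genes tested 0 passed under edgeR and 0 under DESeq2, and 1 had an unadjusted p under 0.05 in edgeR, namely Ank3, with a ratio of 0.19 (SE 0.074, adjusted p = 0.29931) and higher in 3 of 3 libraries.

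The difference between Vax2-low and remaining clusters may reflect the place of the cells in the retina, which was not tested. Of the 10 splits of the 6 sums into 3 and 3, 1 called as many list genes as the real split, namely the real split itself, with 32 called in it and 0 at most in the others. Only 4 of these splits keep a sum of each library on either side, and in the 3 of them that are not the real split at most 0 genes were called. These are too few splits for a share under 0.05. In the other splits the difference between the Vax2-low and remaining sums also enters the spread. Calls of 0 there thus do not tell whether the 32 are sound. When cells were matched on the Malat1 share of their UMIs, 32 of the 32 called genes kept at least 50% of their log2 ratio. This argues against the nuclear RNA share as the cause, as far as Malat1 measures it.

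Sex-linked transcripts differed between the libraries. An Xist UMI, from the RNA that silences an X chromosome in females, was found in 4078 of 6087 horizontal-like cells at P6 (67.0%), in 0 of 2766 at P8, where 3 counts would allow a share of cells with such a UMI of up to 0.108%, and in 1596 of 4343 at P11 (36.7%). Y-linked UMIs without Xist were found in 1735, 2618 and 2691 cells. The Y-linked gene Ddx3y stood at 32.7, 89.8 and 70.4 CPM. At P6, Ank3 stood at 521.5 CPM in cells with only Y-linked UMIs and 538.7 in cells with only Xist, and at P11 at 273.8 and 278.4 CPM.

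Ank2 and Ank3 were lowest at P8, and gene length could account for this as a technical cause. The Ank2 ratio of P8 over P6 was at the 71st percentile of the 100 genes nearest in span and level, which spanned 50.5 to 2271 kb, and that of Ank3 at the 23rd (211 to 1478 kb), while among the 100 genes nearest in span alone (452 to 738 kb and 467 to 824 kb) they were at the 94th and 35th. Matching cells on their Malat1 share left Ank3 at -1.22. As far as Malat1 measures it, this argues against the nuclear RNA share as the whole cause of the Ank3 difference. Whether the matching also removed the trend with gene span was not tested. For Ank2 the matching left -0.24 in place of -0.45, so the nuclear RNA share may carry part of that difference. The matching was done in CPM only, and TMM scaling without matching gave -0.18 for Ank2 and -1.19 for Ank3. The matching therefore cannot tell whether this share is the whole cause for Ank2. In cells with only Y-linked UMIs Ank3 stood at -1.42, which argues against the mix of sexes. Age and any difference between the libraries in which long transcripts were kept or counted stay open.

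The 24 genes with the highest and lowest ratios between P11 and P6 under the naming rule were picked for ratios far above 2-fold, so staying 2-fold apart after a correction excludes little by itself. The shares of cells exclude more. The Vax2-low clusters held 21.8% of the UMIs of horizontal-like cells at P6 and 27.7% at P11, a difference that alone could give at most a 1.27-fold ratio. Cells with only Y-linked UMIs held 29.35% and 62.1%, which could give at most a 2.33-fold ratio when cells of unclear sex are counted so as to make it largest. The smallest of the 24 ratios was 4.52-fold, with an interval from 4.41. This argues against the share of Vax2-low cells and against the mix of sexes as the whole cause. Without the Vax2-low clusters 24 of 24 stayed 2-fold apart, and in cells with only Y-linked UMIs 24 of 24. The Malat1 levels of P6 and P11 differed 1.07-fold, with median shares of 1.87% and 1.88% of a cell's UMIs. In cells matched on Malat1 24 of 24 stayed 2-fold apart and the smallest ratio was 4.516-fold, which argues against the nuclear RNA share, as far as Malat1 measures it. Markers of rod-like, bipolar-like and Müller-like cells were ranked by their level in horizontal-like cells relative to that in the class, and the third lowest limited the RNA of any of these classes to at most 0.162% of the UMIs. Together the classes could give at most 0.587% of the higher level of any of the 24 genes, where at least 77.9% would be needed. After subtraction of the profile of other cells, which took under 1% of UMIs, 24 of 24 stayed 2-fold apart. That profile included the unnamed cells, with 3619254 UMIs at P6 against 234472 in Müller-like cells. Many unnamed cells sat in low-UMI clusters with horizontal cell markers, so the subtraction cannot test RNA from other classes. The limit from markers argues against RNA from those other classes as the cause, while classes without a named cluster had no profile to test. Age and differences between single libraries stay open, since each age had 1.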
